A study of Danio rerio with 3 samples.

How the data were processed

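Total RNA was extracted with Trizol from dechorionated, untreated wild-type zebrafish embryos, and libraries were made by standard Illumina methods, per the labels' protocols. The labels put 1 library in the 6 hpf group and 2 libraries, replicates 1 and 2, in the 10 hpf group. They do not say whether the replicates came from separate clutches or how many embryos were pooled. Reads were processed with TopHat2 2.1.1 and the zebrafish genome build GRCz10, per the submitters' processing notes, and the read counter, gene annotation and filters are not given in the sources used here.

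The data consisted of a single table of 35117 Ensembl genes made by the authors. RPKM values were deposited for 6 hpf and, as 1 value over both libraries, for 10 hpf, per the file headers. A log2 fold change of 10 hpf over 6 hpf and a second, conservative log2 fold (GFOLD with a setting of 0.01) were deposited by the authors, per the file headers. The empirical false discovery rate, a p-value-like column, was also deposited by the authors, and it is 1 wherever the conservative fold is 0. How the fold was scaled is not given in the sources used here. It lies 0.60 below the log2 ratio of the RPKM values at well measured genes, so the fold and the RPKM values rest on different scale factors. The fold also differs from 0 where both RPKM values are listed at 0, and no ratio is given against a listed 0.

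Sequencing depth was inferred from the values. Genes for 5S rRNA have few, similar lengths, and their low RPKM values fall on multiples of what 1 read is worth. With a tolerance of 0.01 bases on the implied lengths, 100% of these values at 6 hpf and 96.8% at 10 hpf were whole reads for totals of 16991524 and 23243177 reads, and the most frequent ratio of 6 hpf to 10 hpf RPKM over genes (1.368, in 342 genes) matches the ratio of these totals (1.37). A single total was fitted to each stage. Pooled reads of both 10 hpf libraries would give such a step, but so would 1 library alone, so the fit does not show pooling. Values per library were not used here, so there is no estimate of the spread between replicates, and neither an SD nor a standard error stands beside any level. Intervals on shares of genes are Wilson intervals at 95% and cover counting error only.

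The design written before the data were examined assumed counts per library, with other tests for normalized values. Because the table held RPKM per stage and the authors' own comparison, the alternative foreseen for that case was used. Genes were counted by an empirical false discovery rate under 0.05 in the authors' deposited table, without a test of the difference made here. A call was regarded as kept after centring where the conservative fold stayed on its side of 0 once the median log2 fold of genes at 5 RPKM or more (−0.50) had been subtracted. This assumes that the distance between the fold and its conservative bound does not change, and a gene that was not called could not become called.

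The 25 gene lists of tissues, pathways and cell states were fixed before the data were examined and matched by the first symbol given for each gene, or by its current symbol in a table of gene names, which held 27000 of the identifiers. Some list members were not matched, and some genes belong to more than 1 list. For each list the median log2 fold of members at 1 RPKM or more was set among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart outside percentiles 2.5 to 97.5. The percentile is a description of these libraries and not a p-value. The procedure was tested on simulated data drawn for this comparison over 17494 genes: 6% of 200 unchanged lists of 20 genes fell outside the central 95%, and 97.5% of lists raised by 1.5 on the log2 scale were recovered. The simulated folds were permuted over genes, so members were independent and folds were unrelated to level. Lists of co-regulated genes, or of fewer members, can stand apart at another rate.

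Genes were named by a rule fixed in advance. Among called genes with at least 5 RPKM in the higher stage and a symbol that is not a clone or locus placeholder, the 8 with the largest log2 fold in each direction were taken, of which 1 is not reported here. From each list up to 3 called members with the largest fold at that level and the 1 member not called with the highest level were added, and for mitochondrially encoded and ribosomal protein genes counts, medians and the most abundant member. A further gene, hoxb1b, was named as the Hox gene with the highest level after its value had been seen. Changes of named genes are given as RPKM pairs or ratios of RPKM values with no pseudocount.

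Alternatives were a minimum of 1 or 5 RPKM, a false discovery rate under 0.01, a minimum absolute log2 fold of 1, folds centred on the median gene, random lists not matched on expression, and pseudocounts of 0.1 and 5. The RPKM ratio with a pseudocount of 1, a count without short noncoding RNAs and the ribosomal list without kinases and like genes were added after the data were seen. Coordinates are not given, because no genome of the build used by the authors was used here. Scripts were run with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.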

Results

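RNA was sequenced from untreated, whole wild-type zebrafish embryos at 6 and 10 hours post fertilization (hpf), the stages at which gastrulation begins and ends. The earlier stage was represented by 1 library and the later stage by 2 libraries. The question was which transcripts differ in level between the start and the end of gastrulation, when the germ layers are laid down and the body axis is formed. Expression was available as a single RPKM value (reads per kilobase of gene, scaled to the total number of reads) per gene and stage, made by the authors, and the 10 hpf value covered both libraries combined. Steps between low values corresponded to 16991524 reads at 6 hpf and 23243177 reads at 10 hpf, so that 1 RPKM stood for about 17.0 and 23.2 reads per kilobase. Of 35117 genes, 17494 reached 1 RPKM and 10692 reached 5 RPKM at either stage, while 7382 were listed at 0 at both.

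Between 6 and 10 hpf, 35 of 48 Hox genes and 16 of 28 neural plate genes were called higher, with 0 and 2 called lower, and 14 of 22 maternal and 13 of 18 blastula-stage genes were called lower, with 0 called higher. The eye-field homeobox gene rx3 went from 0.0417 to 61.8 RPKM, the somite gene meox1 from 0.0425 to 22.6 RPKM and the T-box gene tbx6 from 1.18 to 79.7 RPKM. The pluripotency-associated POU factor pou5f3 went the other way, from 783 to 45.7 RPKM, which is 17.1-fold on the RPKM scale. Of the 25 gene lists fixed before the data were examined, 9 stood above and 3 below the central 95% of random lists matched on expression. A gene was called where its empirical false discovery rate in the authors' deposited table was under 0.05, and a call was given the direction of the log2 fold there.

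By that criterion 10351 genes (29.5%) were called in the authors' deposited table, 3405 of them higher and 6946 lower at 10 hpf. This split depended on the scaling of the fold. The log2 fold in the authors' deposited table lay 0.60 below the log2 ratio of the RPKM values (SD 0.042 over 7009 genes above 5 RPKM at both stages), a factor of 1.52, and its median over genes at 5 RPKM or more was −0.50 against 0.09 for the RPKM ratio. Among genes at 5 RPKM or more that differed at least 2-fold in the authors' deposited table, 1522 were higher and 3735 lower, a share of 29.0% higher (95% Wilson interval 27.7 to 30.2). Centring the folds on the median of these same genes gave 2446 higher and 2546 lower (49.0%), a near balance that such centring tends to produce by itself. The RPKM ratio, which was not centred, gave 2385 higher and 2236 lower (51.6%). Of the genes called lower, 4718 kept the call when folds and their conservative bounds were centred in this way. This step could only remove lower calls and could not add higher ones, so the share of higher calls could only rise. It went from 32.9% to 41.9% of the remaining calls, which is not the share that calls made on centred folds would give. None of the called genes (0) had a direction that differed between the scalings. The smallest absolute log2 fold among calls in the authors' deposited table was 0.79, larger than the shifts between scalings, so this was largely fixed in advance. The medians of gene lists below are therefore given relative to all genes at 1 RPKM or more, whose median log2 fold in the authors' deposited table was −0.41.

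**Figure D1:**
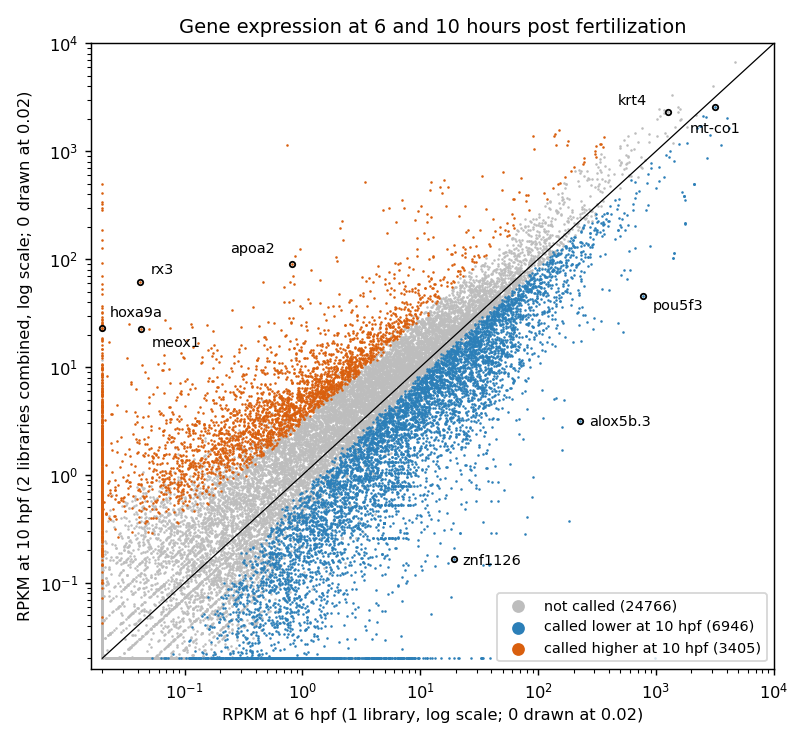
RPKM of each gene at 10 hpf (2 libraries combined, vertical log axis) against 6 hpf (1 library, horizontal log axis), with values of 0 drawn at 0.02. Points are genes called higher (3405, orange), called lower (6946, blue) or not called (grey) in the authors' deposited table, the line marks equal RPKM, and rx3 (0.0417 to 61.8 RPKM) and pou5f3 (783 to 45.7 RPKM) lie far to either side of it.

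By size of the log2 fold in the authors' deposited table, the leading genes at 5 RPKM or more were nr2f5 (ENSDARG00000033172, a COUP-TF-family nuclear receptor), the small nucleolar RNA SNORD33 (ENSDARG00000081926), rx3 (ENSDARG00000052893), hoxa9a (ENSDARG00000105013), hoxc3a (ENSDARG00000070339), fezf2 (ENSDARG00000070677, a forebrain zinc finger factor), hoxc6b (ENSDARG00000101954) and he1a (ENSDARG00000023656, a hatching enzyme). Of these, nr2f5, hoxa9a, fezf2, hoxc6b and he1a were listed at 0 at 6 hpf and at 31.6, 23.2, 22.3, 23.2 and 32.1 RPKM at 10 hpf. Values for hoxc3a were 0.0335 and 24.9 RPKM, and those for SNORD33 were 0.745 and 1132 RPKM. A value near 0.04 RPKM is at the level of a read per kilobase (0.0589 RPKM at 6 hpf and 0.0430 RPKM at 10 hpf), so ratios against such values are not given. In short genes the floor lies higher, so the 0.745 RPKM of SNORD33 at 6 hpf can also rest on very few reads.

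The largest decreases included the orphan receptor gene gpr153 (ENSDARG00000087601), from 12.4 to 0.0513 RPKM, the zinc finger gene znf1126 (ENSDARG00000103458), from 19.2 to 0.165 RPKM, and dlk2 (ENSDARG00000076247), a delta-like gene, from 6.82 to 0.0320 RPKM. A pair of lipoxygenase genes was among them: alox5b.3 (ENSDARG00000069966) fell 70.9-fold, from 226 to 3.19 RPKM, and alox5b.1 (ENSDARG00000043085) fell from 13.8 to 0.178 RPKM. They also included a pair of signal recognition particle RNA loci, Metazoa_SRP (ENSDARG00000102646 and ENSDARG00000101764), which fell from 38.8 and 32.5 RPKM to a listed value of 0. Reads of such multi-copy loci can belong to other copies, so their values are uncertain.

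Of 28 measured genes of the neural plate, 16 were called higher, 2 lower and 10 were not called, and the relative median log2 fold of 2.70 stood at percentile 100 of the random lists. The median itself was 2.29 in the authors' deposited table, 1.34 with members at 5 RPKM or more, and 1.32 on the RPKM ratio with a pseudocount of 5. Besides rx3 and fezf2, the proneural gene neurog1 increased from 0.0422 to 30.3 RPKM. The pan-neural SoxB1 gene sox19a, already abundant at 6 hpf, was not called at 205 and 168 RPKM. Non-neural ectoderm, placode and neural crest border genes had 9 members called higher, 1 lower and 9 not called of 19, with a relative median of 1.32 (percentile 99.99). The ionocyte factor foxi3a was listed at 0 and then at 7.51 RPKM, the neural crest border gene pax3a rose from 0.0921 to 7.17 RPKM, and tp63, a regulator of basal epidermis, rose 16.0-fold from 2.58 to 41.4 RPKM. For tfap2a, which was not called, the values were 53.5 and 85.2 RPKM.

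In the retinoic acid and Hox list 29 of 39 members were called higher, 1 lower and 9 not, and the relative median log2 fold was 5.88 (percentile 100). The median itself was 5.46 in the authors' deposited table, 2.77 on the RPKM ratio with a pseudocount of 1 and 1.34 with a pseudocount of 5. After hoxa9a, the leading members were hoxc8a and hoxb10a, both listed at 0 at 6 hpf and at 29.1 and 24.7 RPKM at 10 hpf. The caudal-type gene cdx4, present at 126 RPKM and then at 340 RPKM, was not called. The fold in the authors' deposited table lies below the RPKM ratio, so a rise in RPKM can go uncalled where a smaller fall is called. The mitochondrial gene mt-co1, for example, was called lower before centring at 3143 and 2548 RPKM. A gene that was not called is thus not shown to be unchanged. Across all 48 Hox genes in the data, 35 were called higher and 0 lower in the authors' deposited table, and 27 of those 35 were listed at 0 at 6 hpf. No Hox gene exceeded 0.953 RPKM at 6 hpf, whereas the highest value at 10 hpf was 123 RPKM, for hoxb1b.

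In paraxial mesoderm and segmentation, 10 of 22 members were called higher, 4 lower (2 after centring) and 8 not, with a relative median of 0.88 (percentile 99.97). Besides meox1 and tbx6, the myogenic factor myf5 rose from 0.998 to 35.2 RPKM, and hes6 was not called at 110 and 161 RPKM. In the list of lateral plate, blood and heart, 7 of 15 members were called higher, 2 lower and 6 not. Only 6 of them reached 1 RPKM, and over these the relative median was 4.17 (percentile 100), which is a median log2 fold of 3.75 in the authors' deposited table against 1.54 over all 15 (percentile 99.9). The leading genes were hoxb5b, listed at 0 and then at 14.7 RPKM, the intermediate mesoderm factor pax8, from 0.0495 to 22.6 RPKM, and the heart and fin mesoderm factor hand2, listed at 0 and then at 9.73 RPKM. Values for gata4, not called, were 3.35 and 10.4 RPKM. Genes of the margin and ventrolateral mesoderm had 0 members called higher, 7 lower (6 after centring) and 11 not called of 18, and the relative median of −0.13 lay inside the range of random lists (percentile 71.3). Lists matched to it on expression had a median log2 fold of −0.71 in the authors' deposited table, against −0.55 for the list itself. The mesendoderm homeobox gene mixl1 fell from 14.8 to 1.54 RPKM, eve1 from 131 to 28.0 RPKM and the T-box gene tbx16 from 123 to 34.4 RPKM, whereas msgn1 of the presomitic mesoderm, at 68.4 and 151 RPKM, was not called.

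Endoderm and organizer genes were divided among directions. Of 11 endoderm genes, 1 was called higher, 4 lower (3 after centring) and 6 not, with a relative median of 0.55 (percentile 96.5). This list passed the upper limit on the RPKM ratio with pseudocounts of 1 (98.06) and 5 (98.9), not with 0.1 (97.3), and lay at 85.2 with members at 5 RPKM or more. The endoderm-specifying factor sox32 fell from 59.4 to 10.3 RPKM and foxa3 from 67.6 to 31.0 RPKM, and the chemokine receptor gene cxcr4a was not called at 65.2 and 64.0 RPKM. In the list of organizer, prechordal plate and notochord, 4 of 18 members were called higher, 5 lower and 9 not (relative median 0.18, percentile 79.0). A pair of genes annotated as ctslb, a cathepsin of the hatching gland, rose 29.3-fold from 9.50 to 279 RPKM (ENSDARG00000039173) and 18.9-fold from 16.5 to 313 RPKM (ENSDARG00000074306), and the copies may share reads. The BMP-related ligand admp fell from 15.6 to 4.04 RPKM, and the BMP antagonist chordin (chd) was not called at 69.1 and 63.6 RPKM.

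Of 22 maternal and oocyte genes, 0 were called higher and 14 lower, 11 of the latter also after centring, and 8 were not called. Only 14 of the 22 reached 1 RPKM, and over these members the relative median was −1.61 (percentile 0.04). That is a median log2 fold of −2.02 in the authors' deposited table, against −1.57 over all 22 (percentile 0.03). The CCCH zinc finger gene cth1 fell from 16.9 to 0.443 RPKM, the cyclin gene ccna1 from 9.34 to 0.430 RPKM and the claudin gene cldnd from 12.2 to 1.88 RPKM, while the abundant RNA-binding protein gene ybx1 was not called at 1449 and 1672 RPKM. Among 18 blastula-stage zygotic regulators, 0 were called higher, 13 lower (10 after centring) and 5 not, with a relative median of −1.13 (percentile 0.43, or 3.95 with members at 5 RPKM or more). After pou5f3, the largest decreases were those of nnr, from 249 to 30.1 RPKM, and foxh1, a transcriptional effector of Nodal signals, from 59.0 to 12.8 RPKM. The ventral repressor gene vox was not called at 116 and 124 RPKM. For 8 primordial germ cell genes, 0 were called higher, 6 lower (4 after centring) and 2 not, with a relative median of −1.57 (percentile 1.68). On the RPKM ratio the list lay inside the central 95%, at percentiles 2.54, 3.55 and 4.02 with pseudocounts of 0.1, 1 and 5. The helicase gene ddx4 (vasa) fell 8.35-fold from 35.6 to 4.26 RPKM and gra fell from 6.97 to 1.14 RPKM. A decrease of nanos3 from 19.1 to 11.6 RPKM was not kept after centring, and tdrd7a was not called at 3.26 and 2.35 RPKM.

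Extraembryonic layers held members that moved in opposite directions. Of 21 genes of the enveloping layer, the outer epithelium of the embryo, 2 were called higher, 8 lower and 11 not. All 8 lower calls were kept after centring. The adhesion gene epcam fell from 122 to 29.9 RPKM, grhl3 from 48.8 to 13.4 RPKM and a keratin gene annotated as krt17 (ENSDARG00000036830) from 51.4 to 16.0 RPKM, whereas krt4, the most abundant member not called, stood at 1274 and 2305 RPKM. The relative median of this list was 0.44, at percentile 98.6 of matched lists and 84.3 of unmatched ones. Among 16 genes of the yolk syncytial layer, 5 were called higher, 7 lower (4 after centring) and 4 not, with a relative median of −0.25 (percentile 47.0). Among its apolipoprotein genes, apoa2 increased from 0.808 to 90.3 RPKM, apoba from 0.204 to 12.5 RPKM and apobb.1 from 1.96 to 95.7 RPKM. For apoeb, an apolipoprotein gene that was not called, the values were 1552 and 2596 RPKM.

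For 6 lists the median and the mean of the log2 fold in the authors' deposited table differed in sign. These were endoderm (median 0.13, mean −0.29), enveloping layer (0.02 and −0.54), yolk syncytial layer (−0.67 and 0.64), FGF signalling (0.11 and −0.07), canonical Wnt signalling (−0.25 and 0.03) and adhesion, matrix and cell migration (−0.11 and 0.30). On the RPKM ratio the medians of margin and ventrolateral mesoderm (0.10), organizer, prechordal plate and notochord (0.32), yolk syncytial layer (0.02), BMP signalling (0.07), canonical Wnt signalling (0.31), planar cell polarity and convergent extension (0.31) and adhesion (0.60) lay above 0, and no direction is given for these lists. Further medians changed in size and kept their sign. With a pseudocount of 5 on the RPKM ratio they were 1.22 for lateral plate, blood and heart (3.75 as deposited), 0.81 for later tissue differentiation (3.10), −0.39 for maternal and oocyte transcripts (−2.02), −0.51 for blastula-stage zygotic regulators (−1.54), −0.34 for primordial germ cells (−1.98), −0.31 for Nodal signalling (−1.06) and −0.16 for cell cycle (−0.85). Ribosomal proteins had 1.18 with a pseudocount of 0.1 (0.52 as deposited), and the non-neural ectoderm list 1.58 without a minimum level, 0.46 with members at 5 RPKM or more and 0.63 with a pseudocount of 5 (0.91 as deposited). With members at 5 RPKM or more, lateral plate, blood and heart had 6.51, paraxial mesoderm and segmentation 0.18 (0.46 as deposited) and primordial germ cells −3.09, while the endoderm median turned negative (−0.25).

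**Figure D2:**
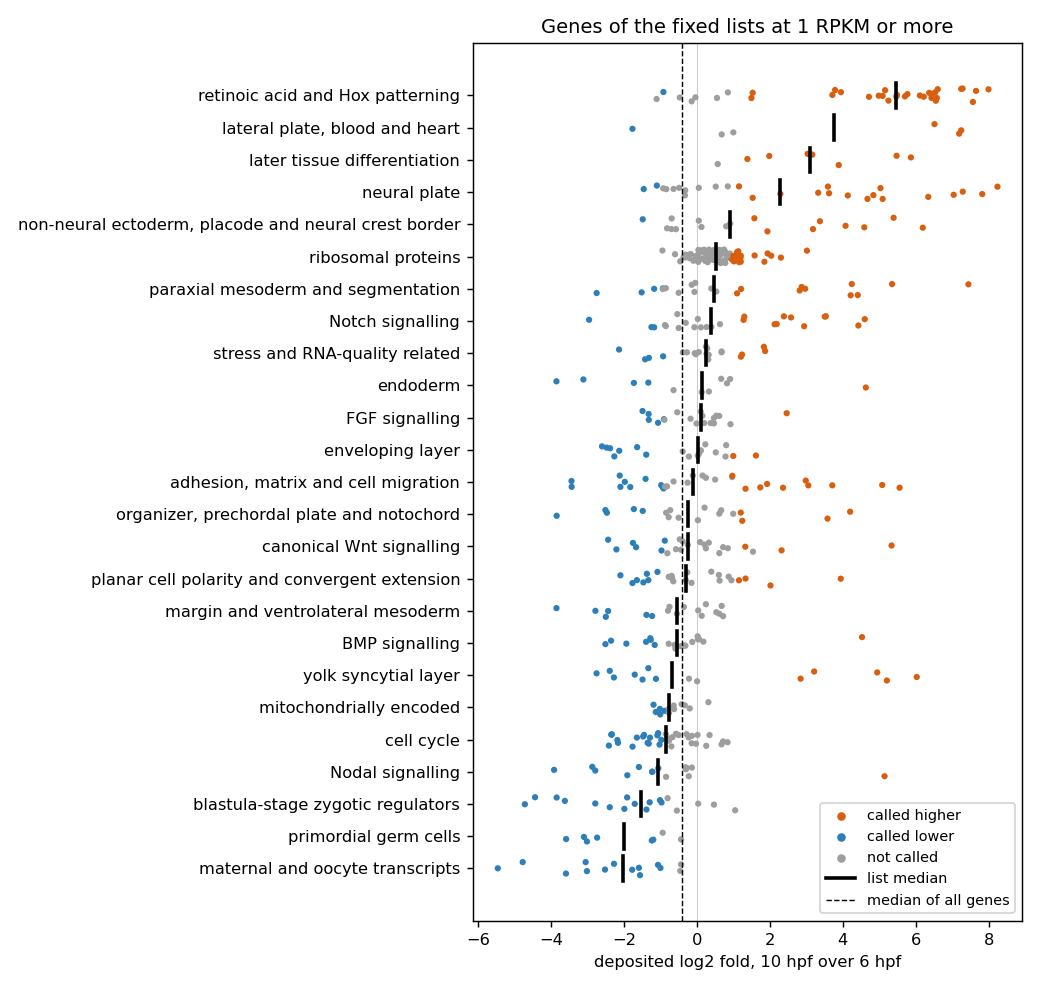
The log2 fold (10 hpf over 6 hpf) in the authors' deposited table for each member at 1 RPKM or more of the 25 fixed lists, in order of list median (black bars); points are genes called higher (orange), called lower (blue) or not called (grey). The dashed line is the median of all genes (−0.41), and retinoic acid and Hox patterning lies farthest to its right, maternal and oocyte transcripts farthest to its left.

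In Notch signalling 11 of 27 members were called higher, 3 lower (1 after centring) and 13 not, with a relative median of 0.81 (percentile 99.9). Its leading members were target genes of the pathway: a pair annotated as her15.1, from 1.11 to 42.3 RPKM (ENSDARG00000054562) and from 0.899 to 16.5 RPKM (ENSDARG00000054560), and her4.1, from 0.246 to 9.83 RPKM, all of which have close copies that may share reads. Nodal signalling had 1 of 15 members called higher, 8 lower (5 after centring) and 6 not (relative median −0.64, percentile 7.58). The Nodal co-receptor gene tdgf1 fell from 93.1 to 18.9 RPKM and the receptor gene acvr1ba from 57.8 to 23.8 RPKM, and smad4a was not called at 14.9 and 19.4 RPKM. Of 21 BMP genes, 1 was called higher, 7 lower (3 after centring) and 13 not, at a relative median of −0.14 (percentile 48.1). The ligand gene bmp7a fell from 57.4 to 17.2 RPKM. A lower call of bmp4, at 11.2 and 6.39 RPKM, was not kept after centring, and the target gene id1 was not called at 337 and 431 RPKM. Of 20 FGF genes, 2 were called higher, 5 lower and 13 not (relative median 0.52, percentile 96.9, or 97.54 without a minimum level), and after centring the receptor gene fgfr1a, from 17.1 to 9.18 RPKM, was the 1 lower call that was kept. Lower calls of fgf17 (9.69 and 5.78 RPKM) and flrt3 (66.6 and 41.5 RPKM) were not kept, and fgfr4 was not called at 68.8 and 96.2 RPKM. In canonical Wnt signalling 3 of 23 members were called higher, 6 lower (4 after centring) and 14 not (relative median 0.17, percentile 86.9). The brachyury gene ta fell from 233 to 65.5 RPKM and the repressor gene tcf7l1a from 66.5 to 22.3 RPKM, while tcf7 rose from 1.75 to 13.3 RPKM.

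Genes of cell movement also went both ways. In planar cell polarity and convergent extension, 4 of 25 members were called higher, 7 lower (6 after centring) and 14 not, with a relative median of 0.11 (percentile 88.0). The cadherin-type receptor gene celsr1b rose from 0.241 to 5.84 RPKM and the Frizzled receptor gene fzd2 from 4.15 to 25.3 RPKM, whereas has2, a hyaluronan synthase, fell from 19.3 to 6.77 RPKM. Another Frizzled gene, fzd7a, was not called at 111 and 229 RPKM. In adhesion, matrix and cell migration, 10 of 31 members were called higher, 10 lower (6 after centring) and 11 not (relative median 0.31, percentile 97.2). On the RPKM ratio the list lay above the central 95%, at percentiles 98.6, 99.05 and 98.2 with pseudocounts of 0.1, 1 and 5, and against unmatched lists it lay at 80.6. The G protein gene gna12a rose from 0.0538 to 5.60 RPKM, the fibronectin gene fn1b from 0.765 to 40.03 RPKM and the protocadherin gene pcdh19 from 1.81 to 36.7 RPKM, and the laminin gene lamb1a was not called at 84.0 and 128 RPKM.

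Cell cycle genes were lower or not called. Of 35 members, 0 were called higher, 17 lower (9 after centring) and 18 not, and the relative median of −0.44 lay inside the range of random lists (percentile 25.1). The G1/S cyclin gene ccne1 fell from 50.6 to 14.1 RPKM, the replication-licensing gene cdc6 from 175 to 53.4 RPKM and ccna2 from 150 to 46.6 RPKM, while pcna was not called at 594 and 607 RPKM. Ribosomal protein genes had 23 of 88 members called higher, 1 lower and 64 not, with a relative median of 0.94 (percentile 100). Without 14 kinases and like genes caught by the same symbol pattern, a step added after the data were seen, 19 of 74 were called higher and 0 lower, and 72 lay above the median of all genes. The most abundant ribosomal member, rps7, was not called at 705 and 1219 RPKM. Of 13 mitochondrially encoded genes, 0 were called higher, 5 lower and 8 not (relative median −0.35, percentile 40.005), and 0 of the lower calls were kept after centring. The most abundant of these, mt-co1, stood at 3143 and 2548 RPKM.

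In the list of later tissue differentiation, 7 of 25 members were called higher, 1 lower and 17 not; 8 of the 25 reached 1 RPKM, with a relative median of 3.51 (percentile 100). The median log2 fold in the authors' deposited table was 3.10 over these 8 and 0.57 over all 25 (percentile 99.9). The keratin gene krt1-19d was listed at 0 and then at 9.76 RPKM, the transferrin gene tfa rose 13.1-fold from 23.8 to 313 RPKM and the actin gene actc1a rose from 18.1 to 113 RPKM. A globin gene, hbae1, was not called at 1.46 and 3.37 RPKM. Stress and RNA-quality genes had 4 members called higher, 4 lower (1 after centring) and 16 not of 24, with a relative median of 0.67 (percentile 96.6). The growth arrest gene gadd45ba fell from 52.4 to 17.8 RPKM and the chaperone gene hsp90aa1.1 rose from 1.51 to 8.61 RPKM. A lower call of ddit4, at 80.4 and 51.2 RPKM, was not kept after centring, and hspb1 was not called at 1161 and 2279 RPKM.

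Short noncoding RNAs also differed between the stages, and their classes went in different directions. Among box C/D small nucleolar RNAs at 1 RPKM or more, 49 of 91 were called higher and 6 lower, and the summed level of the class rose from 1934 to 15828 RPKM. Box H/ACA RNAs had 23 of 68 called higher and 2 lower. In contrast, 193 of 246 U small nuclear RNA loci were called lower and 0 higher (summed level 1451 and 158 RPKM), as were 50 of 53 signal recognition particle RNA loci (837 and 12.02 RPKM). Of 156 loci of 5S rRNA, 67 were called lower and 1 higher. These classes were chosen after their values had been seen. In genes this short, 1 RPKM stands for only a few reads (the most common length inferred for 5S rRNA at 6 hpf was 117 bases). The counts can therefore include loci near the floor.

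The calls are those of the authors' deposited table, and no test of the difference was run here, because the 10 hpf libraries appear as 1 combined value and 6 hpf has 1 library. The spread between batches of embryos is therefore unknown, the percentiles describe these libraries alone, and no adjustment over the list alone could be made from the deposited rates.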

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

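The RPKM ratio, the count without short noncoding RNAs and the ribosomal list without like genes were chosen after the data were seen. Of 10351 calls, 5344 remained among genes at 5 RPKM or more (1481 higher, 3863 lower), because fewer genes reach that level. Requiring as well an absolute log2 RPKM ratio of at least 1, with a pseudocount of 1, left 5813 calls, 3147 of them lower, against 6946. With that pseudocount no gene under 1 RPKM at both stages can pass, so part of this drop comes from the pseudocount. The share higher among genes changed at least 2-fold moved from 29.0% to 49.0% after centring and to 51.6% on the RPKM ratio, the first by subtracting the median fold of −0.50, the second with values that lie 0.60 higher and a pseudocount of 1. Centring on the median of the same genes tends by itself to bring the share near balance. Other settings left the count within 1.5 times: 8603 calls at 1 RPKM or more, 9130 at a rate under 0.01, 10094 with an absolute log2 fold of at least 1, 8123 kept after centring and 9953 without short noncoding RNAs. Between 11 and 13 lists stood outside the central 95% over the alternatives, against 12, and 9 did so on the same side in every one. These were neural plate, non-neural ectoderm, paraxial mesoderm, lateral plate, retinoic acid and Hox, Notch, later differentiation, ribosomal proteins and, below, maternal transcripts. Some of them share members, such as hes6 in paraxial mesoderm and Notch and hoxb5b in lateral plate and Hox, so they are not independent results. None of the called named genes (0) changed sign with the scaling, and 8 that were not called did (ybx1, hes6, fgfr4, smad4a, id1, lamb1a, pcna and vox). Calls had absolute log2 folds of at least 0.79 in the authors' deposited table, more than the shifts between scalings, so the result for called genes was largely fixed in advance. Not run, since they need counts or values per library, were other size factors, count tests, the list test with an estimated correlation, replicate 1 against replicate 2 and leaving out each 10 hpf library. No paired analysis was possible because the groups share fewer than 2 replicate numbers and the values are 1 per stage. Depth limits low genes: 1 read per kilobase is worth 0.0589 RPKM at 6 hpf and 0.0430 RPKM at 10 hpf.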

Other observations

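All tests in this part but that of shared reads were chosen after the result was seen, as were the gene families below, which are groups of 12 or more genes at 1 RPKM or more with the same symbol stem, and the members named from them.

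Among these families, zinc finger genes had the most lower calls. Of 321 genes whose symbol starts with znf, 237 were called lower (209 also after centring) and 13 higher in the authors' deposited table, and their relative median log2 fold of −1.64 stood at percentile 0 of 2000 random lists. Members at high levels at 6 hpf included znf1061, which fell from 78.1 to 6.05 RPKM, and znf1072, from 44.2 to 2.17 RPKM. Histone genes (hist) had 15 of 26 called lower (9 after centring) and 0 higher, at percentile 0.05. Most of these lower calls were of genes under 5 RPKM at both stages. A copy of hist1h4l (ENSDARG00000091011) fell from 7.73 to 0.965 RPKM, and another (ENSDARG00000089044) was also called lower. The more abundant hist2h2l (21.4 and 17.5 RPKM) and hist2h3c (16.7 and 13.8 RPKM) were not called. A further hist1h4l copy (ENSDARG00000089737) was not called either, at 7.36 and 4.96 RPKM. The bloodthirsty-related genes (btr) had 10 of 14 called lower, all 10 kept after centring, and 2 higher (percentile 0.60). Here too, most of the lower calls were of genes under 5 RPKM at both stages.

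Other families had more higher than lower calls. Of 18 her genes, which encode Hairy-related repressors, 14 were called higher and 1 lower, with a relative median of 3.17 (percentile 100). Several of these genes, such as her4.1, her9 and her15.1, are also in the Notch list, so the 2 results are not independent. The midbrain-hindbrain boundary gene her5 rose from 0.577 to 25.6 RPKM and her9 from 6.56 to 78.7 RPKM. The UDP-glucuronosyltransferase genes (ugt), a family of conjugating enzymes, had 8 of 14 called higher and 2 lower (relative median 1.68, percentile 99.85), with ugt1b1 rising from 3.71 to 21.0 RPKM. Near-identical members can share reads, so their calls are not independent. Genes with the stem atp had 21 of 68 called higher and 12 lower (relative median 1.03, percentile 100).

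A first pattern is the excess of lower over higher calls. With the scaling of the deposited fold, 29.0% of genes changed at least 2-fold at 5 RPKM or more were higher, and with RPKM values scaled to total reads the share was 51.6%, so the excess may come from the scaling. From 1 RPKM or more to 20 RPKM or more, the share of higher genes went from 35.2% to 19.6% on the deposited fold, from 53.2% to 38.7% after centring and from 54.0% to 43.2% on the RPKM ratio. These shares do not separate an effect of the greater number of reads at 10 hpf, which stays open. No spike-in values were used here, so a net change in RNA content per embryo between the stages stays open.

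A second pattern is that several multi-copy groups, chosen after their values were seen, were mostly called lower. These were 237 of 321 zinc finger genes (209 after centring), 15 of 26 histone genes (9 after centring), 193 of 246 U small nuclear RNA loci and 50 of 53 signal recognition particle RNA loci. Other groups with close copies differed. Of 18 her genes 14 were called higher and 1 lower, and of 14 ugt genes 8 were called higher and 2 lower. Among 156 loci of 5S rRNA, 67 were called lower and 1 higher. If reads shared between near-identical copies had been kept at 6 hpf and dropped at 10 hpf, other genes with a repeated symbol should have fallen too. Their median log2 fold was 0.143 above that of all genes (287 genes under 157 symbols, 95% bootstrap interval −0.055 to 0.39, 57 called higher and 91 lower), so no such fall was seen among them. A repeated symbol does not show that copies share reads, and short noncoding RNA, zinc finger and histone names were left out. Loss of shared reads therefore stays open for the groups that were mostly called lower. More RNA without a poly(A) tail in the 6 hpf library stays open for the small RNA loci, because other classes without a tail went both ways, from −0.53 relative to all genes for 7 small Cajal body RNAs to 2.16 for box C/D RNAs, whose reads can also come from host introns. Capture that differs by RNA class between libraries and clearance of transcripts between the stages were not tested and stay open too.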
